A study of Homo sapiens with 2 samples.

How the data were processed

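Hi-C was performed on HEK293T cells, a human embryonic kidney line that carries the simian virus large T antigen. There was 1 library from cells with the wild-type MED23 gene (WT) and 1 library from cells with the R617Q substitution in MED23, a subunit of the Mediator complex that links transcription factors to RNA polymerase II. Hi-C joins DNA ends that lie close together in the nucleus, so that read pairs count contacts between places in the genome. Per the labels' protocols, chromatin was cut with 100 units of the restriction enzyme MboI, the ends were filled in with biotin-labelled nucleotides, and the blunt ends were ligated for 4 h. The DNA was sheared to fragments of about 400 bp, and biotinylated DNA was captured on streptavidin beads. About 500 ng of bead DNA was amplified for 5 cycles.

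The authors' deposited file for each library is a list of domains, that is, stretches of a chromosome called as topologically associating domains from the contact map. Each list gives only a chromosome, a start and an end per domain in 6 columns, of which columns 4 to 6 repeat the columns before them. The deposited lists carry no score, contact count, insulation value or q-value. The submitters' processing notes name HiC-Pro, Bowtie2 and the genome build hg19. The domain caller, its settings and the versions of the tools are not given in the sources used here. Whether the domains were called from a single library or a pool is not stated, and the labels give 1 library per genotype. The number of read pairs behind each list is unknown, so no depth, depth-based precision or detection limit is given.

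All listed coordinates were multiples of 50 kb, which was taken as the bin of the contact map. In both lists the end of each domain and the start of the next lay exactly 1 bin apart, at 4447 of 4447 places in WT and 4396 of 4396 in R617Q. Such a place is called a junction here, and its position is the listed end of the domain before it. The 50 kb space can be a boundary bin or can arise if the listed end is the first base of the last bin of the domain. In the second reading every domain is 50 kb longer and adjacent domains touch. Starts are printed 1-based. The available gene table is of GRCh38.p14, another build than the hg19 of the submitters' processing notes, so its coordinates were not used with the lists. No annotation or sequence of hg19 was used here, and regions are therefore given by position. Where the text says that a region holds a centromere, this is general background on hg19 and was not computed. The planned placement of gene start sites, gene lists and MED23 itself was not analysed here.

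The analysis was written in Python 3.11.15 with NumPy 2.4.6 and SciPy 1.17.1. Exact duplicate entries were looked for, and there were 0 in either list. A boundary was a distinct domain edge, so that each junction contributes its 2 sides. An edge was matched if any edge of the other list, start or end, lay within 1 bin (50 kb), and was library-specific otherwise. A WT domain was kept if 1 R617Q domain had both its start and its end within 1 bin. A merged domain was an R617Q domain with both edges matched and with 1 or more WT edges in its inside, more than 1 bin from both ends and with no R617Q edge within 1 bin. A split domain was a WT domain that met the same definition with the lists exchanged. Shares carry 95% Wilson intervals, and the medians carry distribution-free binomial intervals. These intervals cover counting error over edges or domains only, which are not independent of one another. Chance matching was described by 1000 circular shifts of the R617Q domains along each chromosome with a fixed seed.

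With 1 library per genotype there is no estimate of the spread between libraries of the same genotype. No p-value was therefore computed, and each difference describes these 2 lists and has no replicate check. The library-specific edges and the merged and split domains named in the results followed a rule fixed before the data were examined. The longest domains, the chromosomes singled out and the regions named only in the closing observations were chosen after their values were seen. The rule took the 10 library-specific edges of each list that lay farthest from any edge of the other list, and the 5 longest merged and 5 longest split domains. Alternatives fixed before the data were examined were matching at 0, 2 and 5 bins, autosomes alone, removal of the shortest 10% of domains, removal of the outermost edges of each chromosome, and reciprocal overlap of 80% or 50% for kept domains. The further alternatives were chosen after seeing the data. They were counting each junction once, reading the listed end as the start of the last bin, removing domains of 3 Mb or longer, and requiring inner edges of merged and split domains to lie over 2 bins from both ends. The merging and matching code was tested on simulated data, in which 398 junctions were removed at random from the WT list of 4470 domains. It recovered 100% of them with 0 false merged domains. The simulation removed whole junctions and displaced none. It therefore checks the code and gives no rate of false merged domains for the real lists.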

Results

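Chromatin domains were mapped by Hi-C in HEK293T cells with wild-type MED23 and in HEK293T cells with the R617Q substitution in this Mediator subunit, with 1 library per genotype. The WT list held 4470 domains and the R617Q list held 4419, on the same 22 autosomes and the X chromosome. The comparison addressed whether the substitution alters chromatin interactions, here as far as the positions of domains show them. Read depth is unknown for both libraries, and no difference below has a replicate check.

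The domains of the 2 libraries had the same median length and covered the same amount of the genome. The median was 500 kb in both lists (95% interval from 500 to 500 kb in each, on the 50 kb grid), and the quartiles were 350 and 700 kb in both. R617Q had 51 fewer domains than WT, a change of -1.14%. The mean length was 601 kb in WT and 608 kb in R617Q. The listed domains covered 2688 Mb in each library, or 92.4% of the span from the first to the last domain of each chromosome. The rest of the span is the 1-bin spaces at the junctions, so this coverage follows from the form of the lists. R617Q had fewer domains under 500 kb, 2042 against 2106 in WT, but not at every short length. Domains of up to 300 kb numbered 873 in WT (19.5% of domains) and 812 in R617Q (18.4%). At 300 kb, the commonest length in WT, there were 513 WT and 460 R617Q domains. The difference went the other way at 250 kb, with 301 and 306, and at 400 kb, with 357 and 384. The 300 kb bound and the single lengths named here were not among the settings fixed before the data were examined.

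**Figure D1:**
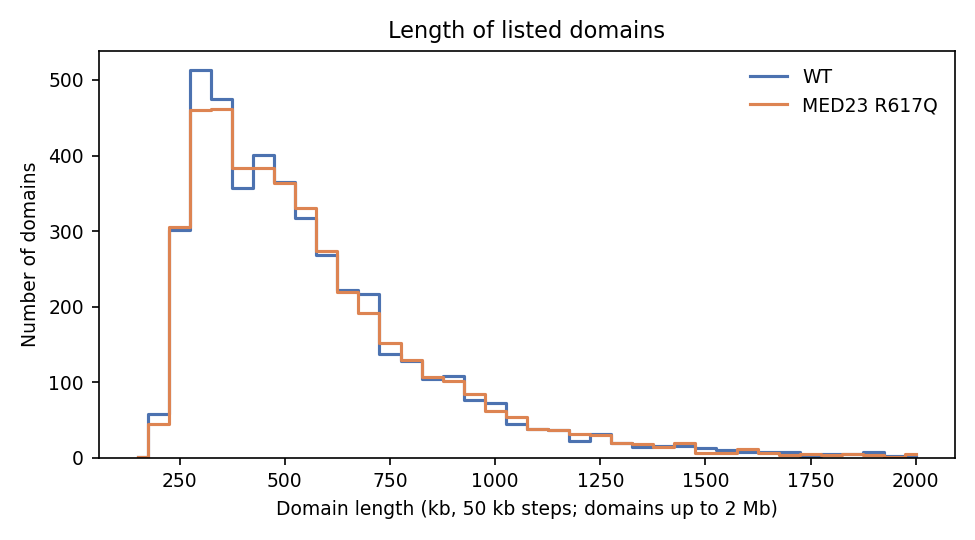
Number of listed domains (vertical axis) by domain length in kb in 50 kb steps (horizontal axis, domains up to 2 Mb) for the WT library (blue) and the MED23 R617Q library (orange). Both distributions have a median of 500 kb, and the clearest gap is at 300 kb, with 513 WT and 460 R617Q domains; 38 WT and 41 R617Q domains longer than 2 Mb are not drawn.

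The 3 longest domains, named after their values were seen, lay at nearly the same places in both libraries. The longest was on chromosome 9, from 38600001 to 71200000 in WT (32.6 Mb) and from 38450001 to 71200000 in R617Q (32.8 Mb). The domains on chromosome 1 from 119650001 to 145050000 (25.4 Mb) and on chromosome 16 from 31500001 to 46500000 (15 Mb) had identical coordinates in both lists. As general background, these stretches of hg19 hold the centromere and the neighbouring heterochromatin, in which few reads can be placed. Domains of 3 Mb or longer numbered 22 in WT and 23 in R617Q, and 10 of the 22 WT domains were kept in R617Q, 9 of them at identical coordinates.

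Most domain boundaries were shared between the genotypes. Of 8940 WT edges, 8116 had an R617Q edge within 50 kb, or 90.8% (95% Wilson interval from 90.2 to 91.4%). Of 8838 R617Q edges, 8109 had a WT edge within 50 kb, or 91.8% (from 91.2 to 92.3%). In 1000 circular shifts of the R617Q list the corresponding shares averaged 30.4% (range from 26.6 to 34.5%) and 30.8% (range from 26.9 to 34.9%), and 0 shifts reached the observed values. Counted once per junction, which was chosen after seeing the data, 3128 of 4447 WT junctions stood at exactly the same coordinate in R617Q (70.3%) and a further 868 stood 1 bin away (19.5%). Of the remaining WT junctions, 73 (1.64%) stood 2 bins away, 80 (1.80%) 3 to 5 bins away, 220 (4.95%) 6 to 10 bins away and 78 (1.75%) over 10 bins away. The share at exactly the same coordinate fell steeply when an offset was added to the WT positions. It was 10.1% and 9.38% at offsets of -50 and 50 kb, and 8.12% at an offset of -1000 kb.

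**Figure D2:**
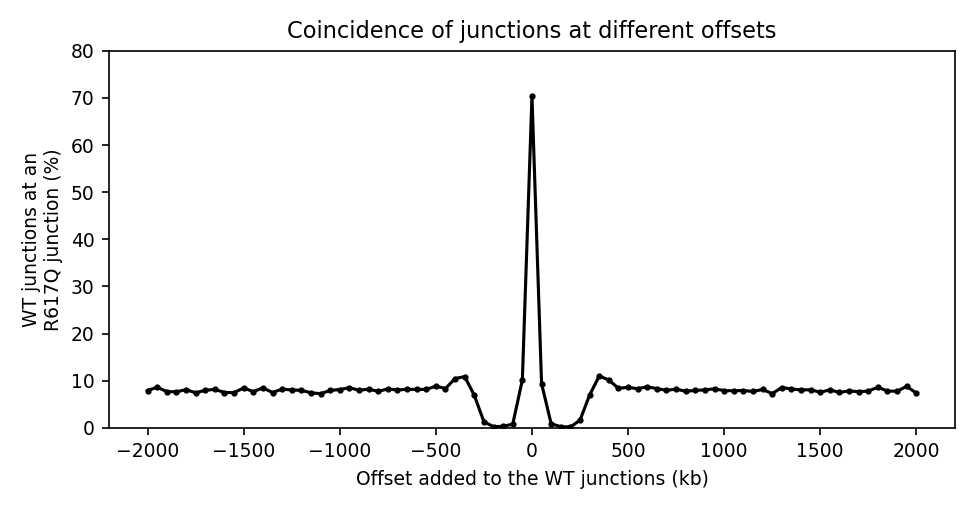
Percentage of WT junctions that coincide exactly with an R617Q junction (vertical axis) after an offset in kb is added to the WT positions (horizontal axis, in steps of 50 kb). The share is 70.3% at offset 0 and 10.1% and 9.38% at -50 and 50 kb, with low values between about 100 and 250 kb on either side, where few domains are that short.

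Whole domains were kept less often than single edges were matched, which follows from the definitions, since a kept domain needs both ends matched. Both ends lay within 50 kb for 3466 of 4470 WT domains, or 77.5% (95% Wilson interval from 76.3 to 78.7%), against a mean of 4.42% and a highest value of 8.97% in the 1000 shifts. At identical coordinates, 2189 WT domains were found again. The share kept depended on domain length. It was 76.1% (from 71.4 to 80.2%) for 360 WT domains under 300 kb and 84.0% (from 82.2 to 85.7%) for 1746 domains of 300 kb to under 500 kb. It was 77.4% (from 75.5 to 79.2%) for 1944 domains of 500 kb to under 1 Mb and 53.0% (from 48.1 to 57.9%) for 398 domains of 1 Mb to under 3 Mb.

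The chromosomes differed in how well the lists matched. The X chromosome had the lowest share of matched WT edges, 85.0% (95% Wilson interval from 81.1 to 88.2%) of 386 edges, and the lowest share of kept domains, 66.3%. Chromosome 14 had the highest share of matched WT edges, 95.5% (from 92.4 to 97.3%) of 288 edges, and the highest share of kept domains, 86.1%. The median WT domain length was 600 kb on the X chromosome and 450 kb on chromosome 14. Since the share kept also varied with domain length, the contrast between these chromosomes cannot be read apart from length. The interval left out the genome-wide WT share on 4 of 23 chromosomes. Both sides of each junction enter these intervals as separate edges, which makes them too narrow. R617Q had fewer domains than WT on 15 chromosomes, more on 7 and the same number on 1. Chromosome 3 had the largest deficit, with 316 domains in WT and 306 in R617Q. Chromosomes 9 and 21 had the largest gains, from 180 to 188 and from 50 to 58 domains. On chromosome 21, 94.0% (from 87.5 to 97.2%) of 100 WT edges were matched in R617Q, and 81.0% (from 73.0 to 87.1%) of 116 R617Q edges were matched in WT.

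**Figure D3:**
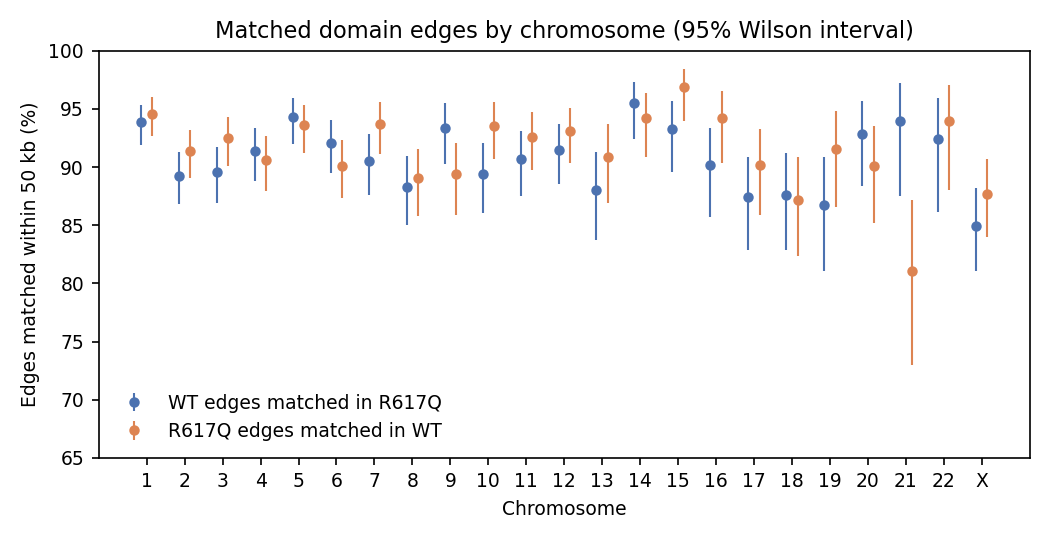
Percentage of domain edges with an edge of the other library within 50 kb (vertical axis, which starts at 65%) for each chromosome (horizontal axis), with WT edges in blue, R617Q edges in orange and 95% Wilson intervals as bars. The X chromosome has the lowest WT value (85.0%) and chromosome 21 the lowest R617Q value (81.0%).

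Merged domains were slightly more numerous than split domains, a difference that is not independent of the lower number of domains in R617Q. There were 263 merged domains in R617Q, with a median length of 850 kb, and 227 split domains of WT, with a median length of 950 kb. In the circular shifts of the R617Q list, merged domains averaged 226 (range from 182 to 280) and split domains 220 (range from 169 to 277). Both observed counts lay inside these ranges, the merged count at percentile 99.5 and the split count at percentile 66.8. Shifted lists shared far fewer edges with WT than the unshifted list did. The shifts therefore give no rate of false merged or split domains. A single WT junction was missing inside 245 of the merged domains, and a single R617Q junction was added inside 216 of the split domains. A junction displaced by 2 bins can meet these definitions. With inner edges required to lie over 2 bins from both ends, chosen after seeing the data, 202 merged and 172 split domains remained. Whether the merged and split counts differ by more than replicate libraries would was not tested.

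The 5 longest merged domains lay on chromosomes 2, 11, 10 and 7. On chromosome 2, the R617Q domain from 89050001 to 96550000 took the place of 3 WT domains, with WT junctions after 91850000 and 95650000. On chromosome 11, the R617Q domain from 49250001 to 56550000 lay over WT domains from 49200001 to 55550000 and from 55600001 to 56500000. On chromosome 10, the R617Q domain from 37150001 to 43300000 lay over 3 WT domains, with a WT domain of 4800 kb from 38100001 to 42900000 in the middle. These 3 regions hold centromeres in hg19, and the other 2 merged domains of this group do not. Whether those 2 hold other sequence in which few reads can be placed was not assessed. The R617Q domain on chromosome 2 from 3750001 to 6900000 (3150 kb) lay over WT domains of 1800 kb and 1300 kb. The R617Q domain on chromosome 7 from 73200001 to 76250000 (3050 kb) lay over WT domains of 2200, 550 and 200 kb.

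Of the 5 longest split domains, those on chromosomes 6, X and 3 also lay at centromeres. The WT domain on chromosome 6 from 57400001 to 63000000 was divided in R617Q into domains of 900, 4100 and 450 kb. The WT domain on the X chromosome from 57550001 to 63050000 met the definition only because its end was displaced by 2 bins, to 62950000, in R617Q. The WT domain on chromosome 3 from 89900001 to 93750000 was divided into domains of 300 and 3550 kb. Away from centromeres, the WT domain on chromosome 4 from 32350001 to 35900000 (3550 kb) corresponded to 4 R617Q domains of 650, 500, 950 and 1200 kb. The WT domain on chromosome 1 from 187000001 to 190350000 (3350 kb) corresponded to R617Q domains of 1700 and 1600 kb.

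**Figure D4:**
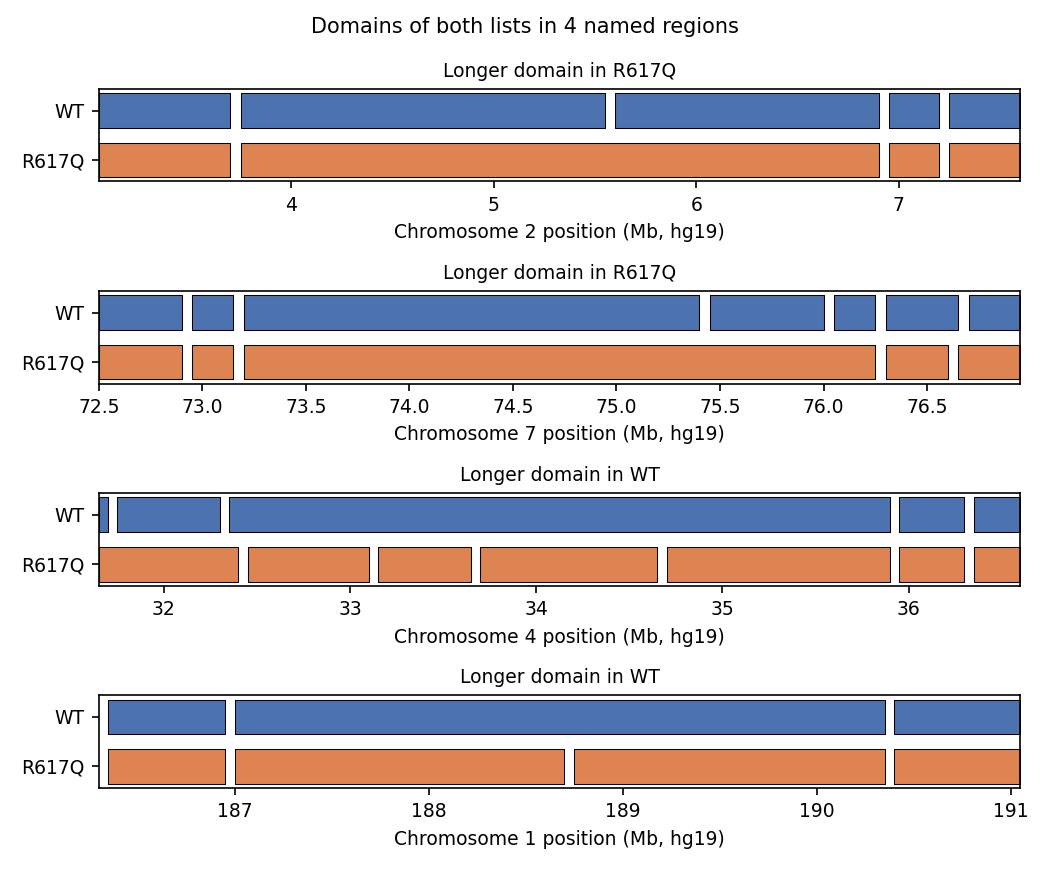
Listed domains of WT (blue, upper row) and R617Q (orange, lower row) against position in Mb (horizontal axis, hg19) in 4 named regions, to scale, with 0.7 Mb on either side. The regions of chromosomes 2 and 7 hold 1 domain in R617Q where WT has 2 and 3, and the regions of chromosomes 4 and 1 hold 1 domain in WT where R617Q has 4 and 2.

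Library-specific edges numbered 824 in WT, or 9.22% (95% Wilson interval from 8.63 to 9.83%), and 729 in R617Q, or 8.25% (from 7.69 to 8.84%). Their median distance to the nearest edge of the other list was 300 kb in both. A distance of 500 kb or more was found for 171 WT edges and 148 R617Q edges. The most isolated WT edges belonged to the junction on chromosome 2 between 91850000 and 91900000, up to 2.85 Mb from any R617Q edge. The next were the junctions on chromosome 10 between 84350000 and 84400000 (1.5 Mb) and on chromosome 2 between 5550000 and 5600000 (up to 1.35 Mb). Those on chromosome 1 between 146850000 and 146900000 (up to 1.3 Mb) and on the X chromosome between 98450000 and 98500000 (up to 1.2 Mb) completed the group. Each lay inside a single R617Q domain of 2.6 to 7.5 Mb. The longest of these, around the first chromosome 2 junction, is the merged domain named above as holding a centromere. The most isolated R617Q edges belonged to the junction on chromosome 1 between 188700000 and 188750000, up to 1.65 Mb from any WT edge. They were followed by junctions on chromosome 4 between 33650000 and 33700000 (up to 1.35 Mb), on chromosome 19 between 24100000 and 24150000 (up to 1.35 Mb) and on chromosome 4 between 34650000 and 34700000 (up to 1.25 Mb). Single edges at 3400000 on chromosome 5 and at 51350000 on chromosome 8, each 1.15 Mb from the nearest WT edge, completed the group. Each of them lay inside a single WT domain of 2.55 to 6.55 Mb, the longest of which held the chromosome 19 edges. The edges of both lists were not screened for sequence in which few reads can be placed.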

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

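Of 89 values under alternatives, 62 stayed within 1.5 times a count or within the interval of a share or median, and 27 moved. There were more merged than split domains in 9 of 9 settings, which all use the same 2 lists and are not independent of the difference of 51 domains. No paired analysis was possible because each genotype has 1 library, and no replicate could be left out for the same reason. Matching at exactly the same coordinate lowered the matched share to 80.1% of WT and 81.0% of R617Q edges and the kept share to 49.0% of WT domains. It raised the library-specific edges to 1779 in WT and 1677 in R617Q, and the merged and split domains to 751 and 716. An end may match a start here, so a junction displaced by 1 bin can still give 1 edge at the same coordinate. Counted by junction, the shares at the same coordinate were lower, 70.3% in WT and 71.2% in R617Q. Matching within 2 bins gave 91.9% and 92.9% of edges and 80.2% of domains. Matching within 5 bins gave 94.3% and 95.2% of edges, 83.3% of domains, and 507 WT and 428 R617Q specific edges. All of these follow from the width of the match. Reciprocal overlap in place of matched ends gave a kept share of 79.6% at 80% overlap and 92.2% at 50%. Without the shortest 10% of domains the kept share was 74.7% and the R617Q median was 550 kb. Leaving out the shortest domains can only hold or raise a median. Domains of equal length at the cutoff were dropped at random, separately in each list. A domain could thus lose its partner, and how much this lowered the kept share was not tested. The next settings were chosen after seeing the data. Counting each junction once gave 4447 WT and 4396 R617Q junctions, of which 89.9% and 90.9% were matched and 451 and 400 were specific, since each junction has a pair of edges. Reading the listed end as the start of the last bin made both medians 550 kb. The covered length was then 2912 Mb in WT and 2909 Mb in R617Q. A stricter selection of domains by score was not run, because the lists carry no score. The gene-based results were not run, because no annotation of hg19 was used here. Read depth is unknown, so its effect on how many junctions each library could show is also unknown.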

Other observations

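The test of chromosome 21, the setting with 250 kb on each side and the rates of specific junctions near and away from very long domains were chosen after the result was seen, and the other tests were set out beforehand. Some differences lay in long stretches with no shared junction. On chromosome 4 from 58300001 to 63550000 (5.25 Mb) there were 5 WT-specific and 3 R617Q-specific junctions and none shared within 1 bin. Chromosome 6 from 49400001 to 52550000 held 4 and 3, and chromosome 21 from 22300001 to 26850000 held 2 and 4. Outside domains of 3 Mb or longer, the longest merged domains were on the X chromosome from 120750001 to 123500000 (2.75 Mb, WT junction after 122850000) and on chromosome 17 from 50300001 to 52950000 (2.65 Mb, WT junction after 51050000). The longest split domains were on chromosome 8 from 49900001 to 52500000 (2.6 Mb, R617Q junctions after 50150000 and 51350000) and on chromosome 5 from 2250001 to 4800000 (2.55 Mb, R617Q junction after 3350000). A split domain on chromosome 21 from 19900001 to 22300000 held R617Q junctions after 20250000, 20800000 and 21850000. These regions were picked after their values were seen.

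Over both lists, 851 junctions had no partner within 1 bin in the other list. Displacement of the same junctions, as the main source, predicts equal numbers from both lists between shared junctions. Equal numbers were found in 24.6% (95% Wilson interval from 21.2 to 28.3%) of the 558 stretches that held a specific junction. WT junctions stood alone in 205 and R617Q junctions alone in 172. Displacement by 1 bin had already been counted as shared. Larger displacement stays open as a partial source, since 129 stretches held 1 junction from each list. A purely thinned list, in which 1 library only lacks junctions of the other, was also not seen. WT held 53.0% (from 49.6 to 56.3%) of the specific junctions. This share follows from the totals of 4447 WT and 4396 R617Q junctions, since 3996 were matched in each direction. A difference in read depth stays open, because depth is unknown and need not act by loss of junctions alone. Unmappable sequence in very long domains stays open as a partial source. Of the specific junctions 5.05% (from 3.77 to 6.74%) lay within 1 Mb of a domain of 3 Mb or longer, against 2.62% of all junctions. The criterion set beforehand against this source, an upper bound under 50%, was met. It could not have been missed, because only 232 junctions of any kind lie there, fewer than 50% of the 851 specific junctions. No conclusion is drawn from that test. Chance differences in calling weak junctions, which may differ between any pair of libraries, and an effect of the genotype both stay open, because there is no second library of either genotype and no junction score.

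Junctions within 1 Mb of a domain of 3 Mb or longer in either list were specific in 18.5% of 232 cases (95% Wilson interval from 14.1 to 24%), against 9.38% (from 8.79 to 10.0%) of 8611 elsewhere. A domain that is this long in one list alone can hold junctions of the other list that are specific by definition, and how much of the difference this accounts for was not tested.

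It was asked whether domains under 500 kb were kept less often because they rest on fewer contacts, and 82.7% (95% Wilson interval from 81.0 to 84.2%) of 2106 were kept, against 73.2% of 2342 domains of 500 kb to under 3 Mb. Within the short domains, however, those under 300 kb were kept less often, at 76.1% (from 71.4 to 80.2%), than those of 300 kb to under 500 kb, at 84.0% (from 82.2 to 85.7%). The additional room in a long domain is a candidate explanation for the lower share of long domains kept. The setting fixed beforehand went against it and a later setting did not, so it stays open. R617Q-specific junctions inside WT domains of 1 Mb to under 3 Mb occurred at 0.33 per eligible Mb (exact 95% Poisson interval from 0.276 to 0.392), above 0.223 (from 0.189 to 0.261) in domains of 500 kb to under 1 Mb, with at least 150 kb left on each side of a junction. These intervals did not overlap, which was the outcome set beforehand as going against room as the explanation. With 250 kb left on each side, chosen after that result was seen, the rates were 0.395 (from 0.328 to 0.47) and 0.369 (from 0.304 to 0.443). At this setting the intervals overlapped. The bound set beforehand used the shortest listed length, which very few domains have. Whether it overstated the room in domains under 1 Mb was not tested.

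Specific WT junctions stood next to each other more often than in the mean of random placements, the direction that clustering would give. Both members were specific in 65 neighbouring pairs of WT junctions, against a mean of 46.3 and a range from 27 to 68 in 1000 random placements within chromosomes. Of these placements, 1 gave as many pairs, so the criterion set beforehand, a value above all placements, was narrowly missed and the test is left undecided. The placements also treated all junctions of a chromosome alike, although specific junctions were more frequent near very long domains. The higher number of domains on chromosome 21 in R617Q, with 12 R617Q-specific against 4 WT-specific junctions, is consistent with chance assignment of junctions to the lists. When the lists were exchanged at random in each stretch, 87.1% of 1000 exchanges gave some chromosome at least as unbalanced, and the imbalance of chromosome 21 ranked 2 of 23.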
